A study of Drosophila melanogaster with 25 samples.

How the data were processed

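RNA levels of imaginal discs of larvae of Drosophila melanogaster were measured on Affymetrix Drosophila Genome 2.0 arrays, with 1 array per sample and 25 arrays in 8 groups. The groups were taken from the sample titles. They were wild-type, UAS-ey and ato-mutant UAS-ey leg discs, wild-type and UAS-ey wing discs, wild-type and Uey antennal discs (3 arrays each), and wild-type eye discs (4 arrays). The labels call the samples biological triplicates. The GAL4 driver, the ato allele and the meaning of the shorter title Uey are not given in the sources used here. Uey was treated as the antennal counterpart of UAS-ey, and group identities rest on the titles.

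Per the labels' protocols, total RNA was isolated with Trizol, and 100 ng per sample went through a two-cycle amplification before biotin labelling of cRNA with an Enzo kit. The deposited values were on a log2 scale, as their range showed. The method that made 1 value per probe set, the software and the scaling between arrays are not given in the sources used here. Every array had the same lowest value, a log2 signal of 6.91 (120.5 on the linear scale), which 25.2% to 33.7% of its probe sets shared, and this was treated as a floor that the authors set. The arrays' medians lay between 7.53 and 7.86, a 1.25-fold spread. That was under the 1.5-fold limit set for renormalizing, so the deposited scaling was kept. Signals ended at 14.33. A change that starts or ends at the floor is therefore a lower bound. Where every array of a group was at the floor, the fold is given as "at least", computed against the floor, and no fold is given where both groups were at it. For these arrays, their number limits the precision.

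The table held 18952 probe sets, of which 183 Affymetrix controls were left out of the tests and 18769 were tested. The platform annotation named 1 gene for 13646 probe sets, several genes for 402 and none for 4721. Only probe sets with 1 gene were named, giving 11981 genes, of which 1094 had several probe sets. Of the 13646 named probe sets, 13543 matched a gene of the RefSeq gene table, and no symbol needed updating. A gene with several probe sets was represented by the one with the highest mean over all arrays. No genome sequence was used here, so no coordinates are given.

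Group differences were tested with limma (version 3.58.1 in R 4.3.3): lmFit with a mean per group on all 25 arrays, contrasts, and eBayes with default settings (17 residual and 0.45 prior degrees of freedom). The tests were two-sided, with Benjamini-Hochberg adjustment over the 18769 probe sets and a threshold of 0.05 on the adjusted p. All adjusted p-values for single genes and for differences between discs come from limma. Log2 changes are followed by their standard errors (SE), and group means by standard deviations (SD). Each SE rests on a spread estimated over all groups, and groups at the floor on every array add no spread to it. For genes at the floor in some groups, SE and adjusted p can therefore understate the spread of the arrays. For gl in wing discs, for example, the SE was 0.17, while the SD of the UAS-ey arrays was 0.56. Differences between discs were contrasts of contrasts in the same fit. Shares of probe sets were compared with Fisher's exact test, two-sided, and carry 95% binomial intervals (exact Clopper-Pearson). These run across probe sets, which are not independent replicates. For the share with the eye disc, the disc whose effect was examined was left out of the eye contrast, so that no wild-type array was shared.

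The comparisons, the tests, 26 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Of 372 list entries, 93 were not measured by a probe set of their own. Lists with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists within a comparison. They were tested again with an estimated correlation and with fry. Genes at the floor on all arrays were left out of set tests. Beside the calls over all probe sets, calls adjusted over the list alone were counted. The rule named 12 measured genes of eye development in every comparison, whatever their test (sca had no probe set of its own). It added up to 8 genes with the largest rise and up to 6 with the largest fall. These had to pass the threshold, show no overlap between the arrays of the groups and have a mean above the median of all values in the higher group. Only the representative probe set of a gene was ranked, and genes known only by a CG or CR number (hairpin and long non-coding RNAs among them) were passed over, some of which changed more than the genes named. Where the text speaks of the largest rises or falls, it means the largest under this rule. It also added the list members with the smallest adjusted p. Genes that the rule named in 1 comparison are given in others too. Dfd, outside the rule, was chosen after its values were seen, and so were the markers of other tissues compared between the eye arrays.

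The alternatives were quantile normalization, centring of each array on its median, a filter keeping probe sets above the 40th percentile, eBayes with trend and robust settings, array weights, a fit on the compared groups only, the replicate number as a block, a 2-fold minimum, the mean of all probe sets of a gene, and leaving out each array in turn. After the data had been seen, further alternatives were added: leaving out probe sets at the floor on all arrays, the signal of the Bacillus phe control probe set as a covariate with its slope estimated within groups, and the eye disc against the antennal disc alone. The relations of the ey and chp signals to the phe control used group-centred values and 100000 permutations, two-sided. Control probe sets separated the arrays into sets that follow the groups. Since every group lies in 1 set, a set term would take up each contrast that crosses the sets, so the covariate was used in its place. Where comparisons shared control arrays, 100 simulations of unchanged groups gave the chance values. For shares between lists that reuse wild-type arrays, the effect in the other comparison was set to 0 for the selected probe sets, and residuals of whole arrays were exchanged in 100 simulations.

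The steps were tested on simulated data with 200 changed probe sets among 18769. The changed ones were drawn from probe sets with a mean above the median of all values. Noise was normal and independent between arrays, with a spread per probe set that all groups shared. Recovery of dimmer probe sets, and under unequal spread or array-wide noise, was thus not tested. At a 2-fold change the fit recovered 93.5% of them for the leg comparison, 93.5% for wing, 94.5% for antenna, 92.5% for ato-mutant against UAS-ey leg, 91% for ato-mutant against wild-type leg and 98.5% for eye. At a 1.5-fold change, recovery was 76% for leg, 73% for wing and 71% for antenna. For differences of 2-fold between discs, recovery was 84% for leg against wing, 86% for leg against antenna and 88.5% for wing against antenna. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.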

Results

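Imaginal discs are the larval epithelia that give rise to the adult appendages and eyes. RNA levels were measured on 25 arrays from larval discs, 1 array per sample. Leg discs came from wild-type larvae, from larvae with a UAS-ey transgene and from ato-mutant larvae with UAS-ey. Wing discs came from wild-type and UAS-ey larvae, antennal discs from wild-type larvae and from larvae titled Uey, and eye discs from wild-type larvae. Each group had 3 arrays, except the eye discs with 4. Eyeless (ey) is a Pax6-type transcription factor of the retinal determination network, and atonal (ato) is the proneural gene that starts photoreceptor formation. The series title names direct targets of Eyeless as its subject. The comparisons ask which genes respond to ectopic ey in discs that form no eye, which of them are also higher in the eye disc, and how loss of ato alters the response in leg discs. Values are log2 signals with a floor at 6.91, and the number of arrays limits their precision.

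The probe set for ey did not follow the transgene. Its mean was 10.59 ± 0.37 (SD, n = 3) in UAS-ey leg discs against 12.04 ± 0.34 in wild-type leg discs, a log2 change of -1.45 (SE 0.27, adjusted p = 9.4e-04). It was 12.43 in UAS-ey and 12.12 in wild-type wing discs, 10.56 in Uey and 10.87 in wild-type antennal discs, 12.53 in ato-mutant UAS-ey leg discs and 10.85 in eye discs. After group means were removed, the ey signal moved across the 25 arrays with that of the Bacillus phe control probe set, which measures a bacterial transcript and no fly gene (Pearson r = 0.750, permutation p = 2e-05; Spearman rho = 0.770, permutation p = 2e-05; adjusted p = 6e-05 for both over 12 relations chosen after the data were seen). The same held for chp, a photoreceptor surface protein gene (r = 0.725, rho = 0.804, permutation p = 1e-05 and adjusted p = 6e-05 for both). Without the 2 arrays farthest from the median of phe, r was 0.736 for ey and 0.778 for chp. Within the 2 array sets described next, r was 0.716 and 0.825 for ey, and 0.687 and 0.889 for chp (permutation, adjusted p at most 0.0055). Levels of ey and chp thus do not check the labels, and their changes are reported only as measured signals. Disc identity genes did separate the discs: Antp was at the floor on all antennal and eye arrays and at 11.32 ± 0.19 in wild-type leg discs. Scr was at the floor on all wing arrays and at 10.70 ± 0.15 in wild-type leg discs. Dfd, chosen after its values were seen, was at the floor in wild-type leg and wing discs and at 11.24 ± 0.03 in wild-type antennal discs. The wing gene vg was at 12.40 ± 0.08 in wild-type wing discs and at the floor in eye discs.

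The phe control also separated the groups. It lay between 7.89 and 9.5 on the 13 arrays of UAS-ey leg, antennal and eye discs, and between 9.77 and 11.15 on the 12 arrays of wild-type leg, ato-mutant UAS-ey leg and wing discs. The values for the cre control were 13.68 to 13.94 and 13.19 to 13.55. The comparisons of UAS-ey leg discs with wild-type or ato-mutant leg discs cross these array sets. So does the comparison of eye discs with leg and wing discs. The wing, the antennal and the ato-mutant against wild-type leg comparisons lie within 1 set. The log2 difference between 3' and 5' GAPDH control signal, a sign of RNA integrity and labelling length, was higher with ectopic ey in all 3 discs, with no overlap of arrays: 2.13 ± 0.13 against 1.84 ± 0.08 in leg, 2.60 ± 0.08 against 2.27 ± 0.25 in wing and 2.28 ± 0.11 against 2.07 ± 0.08 in antennal discs (exact p = 0.1 each, the lowest that 3 against 3 arrays can give). The eIF-4a control did not show this, and its arrays overlapped in all 3 discs. Its 3' to 5' difference was 2.19 ± 0.09 against 2.17 ± 0.14 in leg discs. It was 2.47 ± 0.09 against 2.42 ± 0.10 in wing and 2.40 ± 0.03 against 2.30 ± 0.10 in antennal discs.

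**Figure D1:**
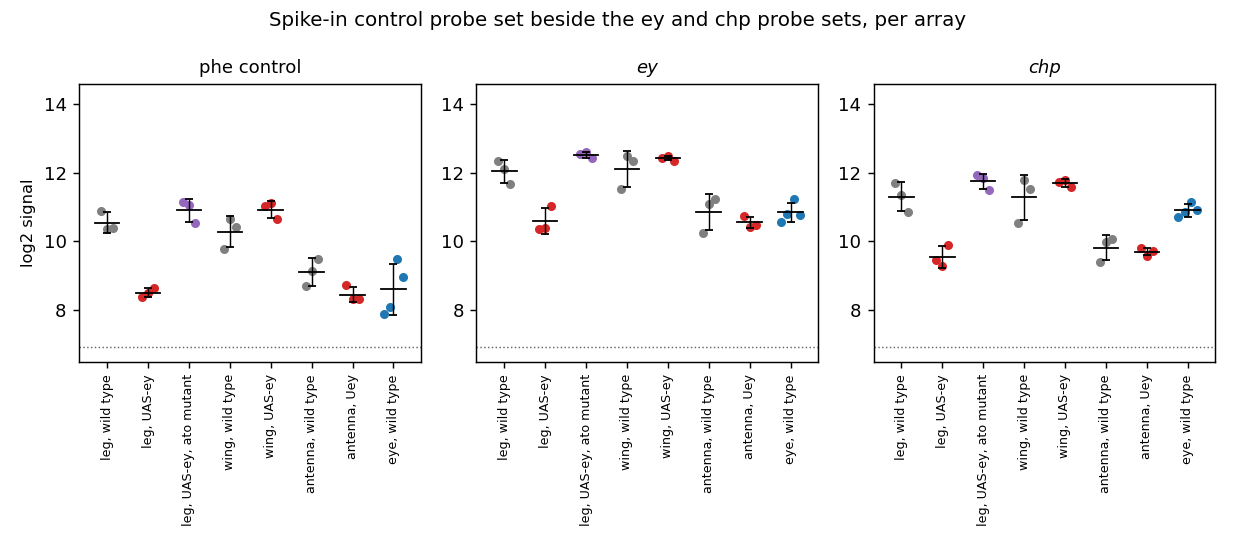
Log2 signal of the phe control probe set, ey and chp on each of the 25 arrays, by group; points are arrays, bars are group means, error bars are SD and the dotted line is the floor at 6.91. The phe signal lies at 9.5 or below in UAS-ey leg, antennal and eye discs and at 9.77 or above in the other groups. chp is at 10.91 in eye discs, above its level in the other groups with a low phe signal.

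In leg discs, UAS-ey raised most of the retinal determination network. The phosphatase and co-activator gene eya rose 15.1-fold, from 8.15 ± 0.15 to 12.07 ± 0.03 (SD, n = 3 each; log2 change 3.91, SE 0.23, adjusted p = 1.5e-09). The homeobox gene so rose by 1.04 (SE 0.20, adjusted p = 0.00103). Genes at the floor on every wild-type leg array rose from it: Optix at least 5.20-fold, the Pax6 gene toy at least 3.62-fold, danr at least 13.7-fold and dan at least 6.63-fold. Dimmer toy probe sets (means 7.22 and 8.03 over all arrays) showed a change of 0 in leg, wing and ato-mutant leg discs. They were higher in the eye disc (1.94 and 3.41). Of the 11 measured retinal determination genes, 7 rose and 1 (ey) fell, with 8 higher and 1 lower when adjusted over the list alone (camera adjusted p = 5.1e-06, and adjusted p = 0.27 with an estimated correlation). For dac the change was 0.23 (SE 0.09, adjusted p = 0.0991).

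Genes downstream in eye development rose in part. The zinc finger gene gl, needed for photoreceptor differentiation, rose at least 8.76-fold, from the floor to 10.04 ± 0.20. ato rose by 1.48 (SE 0.35, adjusted p = 0.00553), and the homeobox gene ro by 0.83. Among 18 photoreceptor and cone genes 3 rose (gl, lz, sev) and 1 (chp) fell, with 3 and 1 adjusted over the list alone (camera adjusted p = 0.569). Of 13 genes of the morphogenetic furrow and R8 specification 3 rose and 0 fell, also when adjusted over the list alone (adjusted p = 0.155). Neither the pan-neuronal gene elav (0.64, adjusted p = 0.0845) nor sens (-0.19, adjusted p = 0.478) nor hh (-0.10, adjusted p = 0.70) passed the test. Of 14 pan-neuronal genes 0 rose and 2 fell, as when adjusted over the list alone. Cell cycle and DNA replication genes rose: 10 of 16, with 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 8.5e-05, adjusted p = 0.398 with an estimated correlation), among them Mcm6 (0.46) and Mcm5 (0.70). In the cell death and stress list, 3 of 9 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.0495, adjusted p = 0.432 with an estimated correlation). Ilp8, the relaxin-like signal that delays metamorphosis, rose at least 11.2-fold, and the JAK/STAT ligand gene upd1 rose by 2.75 (SE 0.16).

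Other large rises were Tektin-C, named for a microtubule protein of cilia and flagella, at least 14.1-fold, the neprilysin-like gene Nepl3 11.2-fold, superdeath at least 11-fold, the cytochrome P450 gene Cyp6a17 at least 10.6-fold and the cuticle gene Cpr49Ah at least 10.4-fold. The largest falls were in Sgs8 (-3.85), GstD3 (-2.96), Sgs3 (-2.90), Spn100A (-2.83), nebu (-2.80) and CSN1a (-2.74). For each of these, all 3 arrays of one group lay above all 3 of the other, which chance gives for 10% of genes. Sgs genes encode salivary glue proteins: of 9 salivary gland markers 7 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.00246, adjusted p = 0.429 with an estimated correlation). Identity genes of several discs moved. Of 14 leg identity genes 6 fell and 0 rose (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0257, adjusted p = 0.398 with an estimated correlation), among them bab1 (-1.04) and Lim1 (-1.08). Of 14 wing identity genes 6 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.0228, adjusted p = 0.432 with an estimated correlation), with vg at -1.41. Another vg probe set changed by -0.09. Of 10 antenna identity genes 4 rose (dan, danr, lz and ato) and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0254, adjusted p = 0.236 with an estimated correlation). Of 14 ecdysone response genes 6 fell and 1, the nuclear receptor gene ftz-f1, rose by 2.01 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0257, adjusted p = 0.398 with an estimated correlation). In total 3632 probe sets changed, 1693 higher and 1939 lower, and 571 did so at least 2-fold, 176 higher and 395 lower. Of the calls 46.6% were higher, against 56.4% after quantile normalization and 55.6% after centring, so the larger group of calls depends on the scaling. With the phe control signal as a covariate, 561 changed, and the calls for eya, Optix, toy, gl, danr, dan, Ilp8, GstD3 and Tektin-C held. Among the 176 rises of at least 2-fold, 119 were still called, and the median change did not shrink (1.47 before, 1.51 after), while the median SE grew from 0.17 to 0.29. Among the 395 falls 54 were still called, and the median change went from -1.51 to -0.39 (SE 0.28 and 0.32). Calls ended mainly by a larger SE for so (0.90, SE 0.35), ato (1.02, SE 0.61), lz (1.64, SE 0.46), Mcm5 (0.54, SE 0.17), Lim1 (-0.76, SE 0.21), ftz-f1 (1.82, SE 0.54), Sgs8 (-3.76, SE 1.16) and Spn100A (-2.20, SE 1.02). They ended mainly by a smaller change for ey (-0.23, SE 0.32), chp (-0.58, SE 0.34) and CSN1a (-0.53, SE 0.36). A fit on the 6 arrays of these groups alone called 2268.

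**Figure D2:**
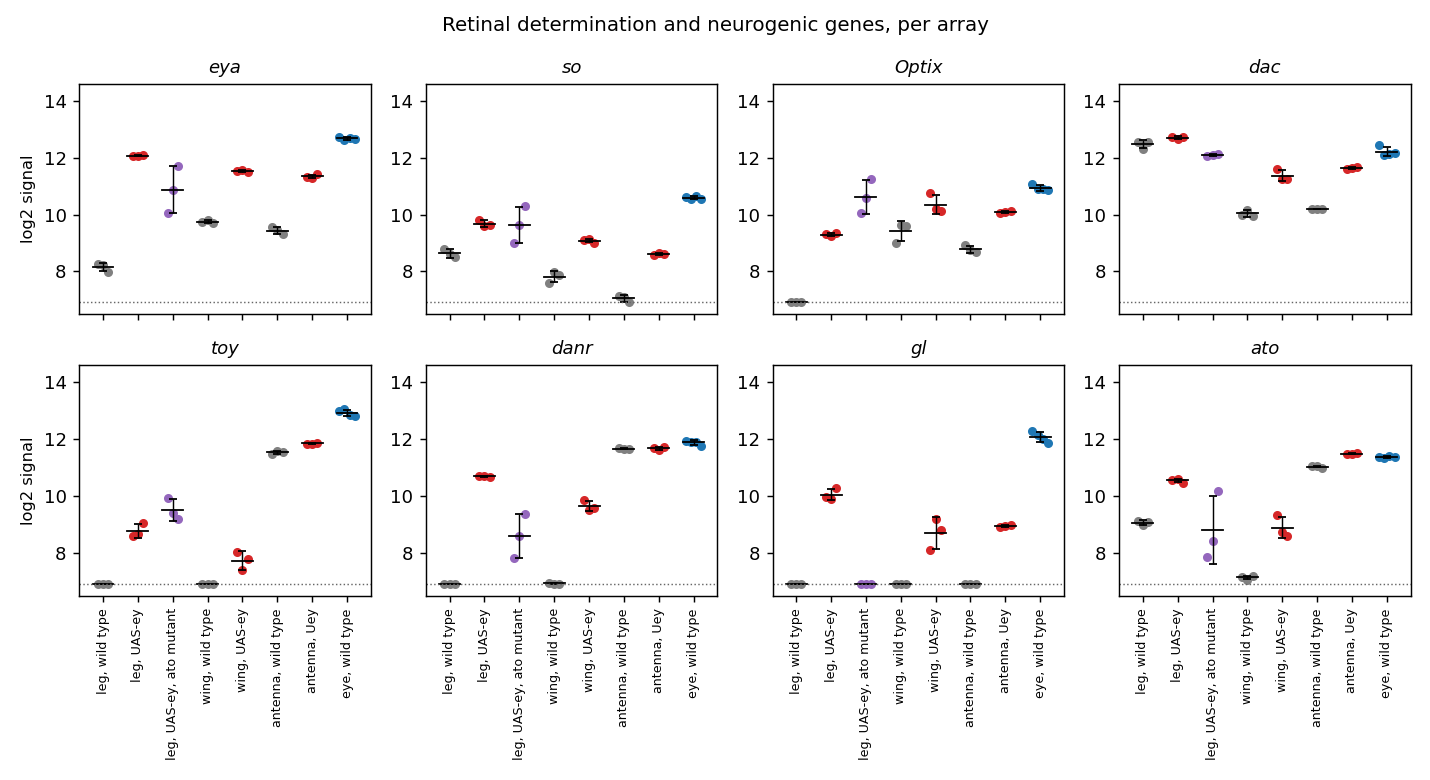
Log2 signal of eya, so, Optix, dac, toy, danr, gl and ato on each array, by group; points are arrays, bars are group means, error bars are SD and the dotted line is the floor at 6.91. The eya signal is 12.07 in UAS-ey leg discs, 8.15 in wild-type leg discs and 12.67 in eye discs, and gl leaves the floor in the UAS-ey and Uey groups and in the eye disc, but not in ato-mutant UAS-ey leg discs.

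In wing discs, UAS-ey raised genes of the retinal determination network, dac among them. eya rose by 1.79 (SE 0.23, adjusted p = 6.9e-05), so by 1.27 (SE 0.20), dac by 1.32 (SE 0.09, adjusted p = 3.0e-08), toy at least 1.77-fold, danr by 2.72 and dan at least 3.74-fold. Optix rose by 0.93 (SE 0.22, adjusted p = 0.0164), a call that was lost without replicate 1 of UAS-ey (0.73) or of wild-type wing discs (0.72). Of 11 retinal determination genes 7 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.7e-12, and adjusted p = 0.0497 with an estimated correlation). Downstream genes rose as well: ato by 1.75 (SE 0.35, adjusted p = 0.00452) and gl at least 3.43-fold. Of 13 furrow and R8 genes 5 rose (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00876, adjusted p = 0.243 with an estimated correlation). Of 18 photoreceptor and cone genes 3 rose and 1 (svp) fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0085, adjusted p = 0.199 with an estimated correlation). Of 14 Notch and E(spl) complex genes, which act in lateral inhibition, 6 rose and 0 fell (7 adjusted over the list alone; camera adjusted p = 1.2e-04, adjusted p = 0.119 with an estimated correlation), among them E(spl)mdelta-HLH (0.55) and E(spl)m4-BFM (0.52).

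Among named genes, the largest rises in wing discs were Tektin-C (at least 3.86 from the floor), Nepl3 11.1-fold, Cyp4p2 at least 9.74-fold, Cpr51A 8.17-fold, chinmo 6.10-fold, superdeath at least 5.88-fold and pst 5.79-fold. The largest falls were GstD3 (-3.05), Sgs8 (-2.99), Kmn1 (-2.43), Sgs3 (-2.36) and Sgs7 (-2.30), and vis fell to the floor, at least 4.27-fold. The call for Sgs7 was lost without replicate 1 (-2.29) or 3 (-2.02) of UAS-ey wing discs or without replicate 1 of wild-type wing discs (-1.69). Salivary gland markers fell in 4 of 9 cases, also adjusted over the list alone (camera adjusted p = 0.0069, adjusted p = 0.397 with an estimated correlation). Of 14 wing identity genes 3 fell, the T-box genes Doc1, Doc2 and Doc3 (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0163, adjusted p = 0.397 with an estimated correlation). Ilp8 rose at least 1.78-fold, upd1 by 0.82 and the pro-apoptotic gene skl at least 3.46-fold (3 of 9 cell death and stress genes rose; 3 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0163, adjusted p = 0.277 with an estimated correlation). Of 16 cell cycle genes 0 rose and 1 (aurB) fell, also adjusted over the list alone. The changes for elav (0.73, adjusted p = 0.117), sens (-0.42, adjusted p = 0.145), hh (-0.12, adjusted p = 0.784) and chp (0.42, adjusted p = 0.563) did not pass. Leaving out UAS-ey replicate 3 (0.96) or wild-type replicate 2 (1.06) made elav a call, and leaving out UAS-ey replicate 2 did so for sens (-0.60). In total 999 probe sets changed, 552 higher and 447 lower, 116 and 27 of them at least 2-fold. After quantile normalization 540 were higher and 547 lower. A fit on the 6 wing arrays alone called 138, and array-wise centring gave 625.

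In antennal discs, Uey raised eya by 1.90 (SE 0.23, adjusted p = 1.7e-05), so by 1.56 (SE 0.20), dac by 1.43 (SE 0.09) and Optix by 1.32 (SE 0.22), and gl at least 4.09-fold from the floor. toy (11.53 ± 0.07 in wild type, change 0.32, adjusted p = 0.259), ato (11.03 ± 0.03, change 0.45, adjusted p = 0.614), danr (11.66, change 0.02) and dan (10.25, change 0.12) were already above their leg and wing levels in the wild type and did not pass. Of 11 retinal determination genes 4 rose and 1 (eyg) fell, also adjusted over the list alone (camera adjusted p = 0.0577). elav rose by 0.95 (SE 0.25, adjusted p = 0.0164), sens fell by 0.70 (SE 0.15) and hh by 0.41 (SE 0.11, adjusted p = 0.0152). The calls for elav and hh were lost when single arrays were left out, with elav not called without Uey replicate 2 (0.88) or 3 (0.86) or wild-type replicate 1 (0.87) or 2 (0.95), and hh not called without Uey replicate 2 (-0.39) or wild-type replicate 1 (-0.37). chp did not pass (-0.11, adjusted p = 1). Notch and E(spl) complex genes rose in 6 of 14 cases (8 adjusted over the list alone; camera adjusted p = 9.5e-04, adjusted p = 0.47 with an estimated correlation), such as E(spl)m7-HLH (0.69) and E(spl)m3-HLH (0.52). Cell cycle genes rose in 6 of 16 cases, also adjusted over the list alone (camera adjusted p = 0.0204, adjusted p = 0.622 with an estimated correlation), such as Mcm2 (0.38).

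Among the largest rises in antennal discs were genes of the adult flight muscle: the actin gene Act88F at least 81.1-fold, flightin (fln) at least 53.0-fold, the troponin C gene TpnC4 at least 25.2-fold and Mlc1 from 8.33 ± 0.05 to 12.24 ± 0.03. In the list of muscle precursor markers, 4 of 8 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0847). Mlc2 rose at least 10.9-fold and Tm2 by 1.15, whereas the mesodermal gene twi fell by 0.68. Other large rises were Pxt at least 26.9-fold, Cyp4p2 at least 15.4-fold, Tektin-C (at least 3.87 from the floor) and Nepl3 (3.81). GstD3 fell by 3.64, Zip102B by 2.09 and ea by 2.06. spok, PPO1 and vis fell to the floor, at least 8.02-fold, 6.48-fold and 4.62-fold. Ilp8 rose at least 5.21-fold and upd1 by 0.91. In total 2160 probe sets changed, 1322 higher and 838 lower, 213 and 58 of them at least 2-fold. The Uey arrays were the most alike of any group (SD of the difference between arrays 0.092 to 0.132). A fit on the 6 antennal arrays alone called 4114.

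**Figure D3:**
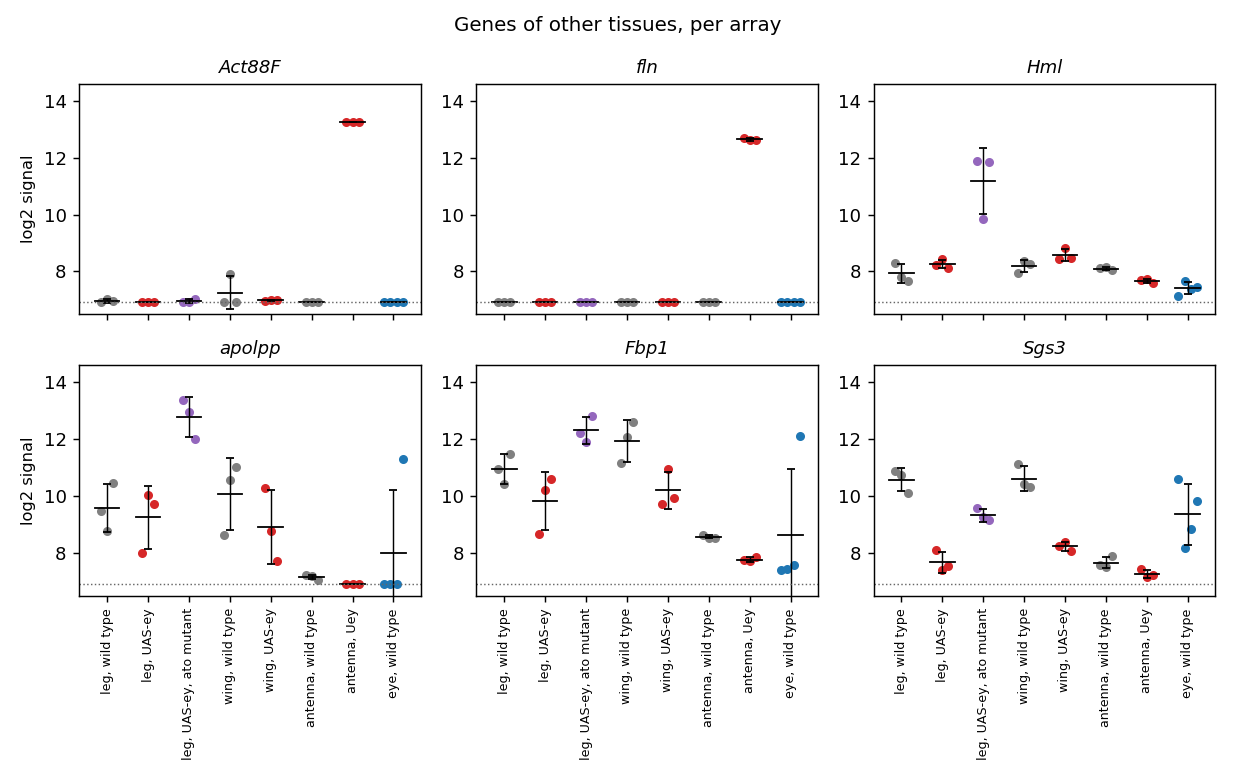
Log2 signal of 6 genes known from other tissues on each array, by group: the adult flight muscle genes Act88F and fln, the haemocyte gene Hml, the fat body genes apolpp and Fbp1 and the salivary gland gene Sgs3. Points are arrays, bars are group means, error bars are SD and the dotted line is the floor at 6.91. Act88F is at 13.26 in Uey antennal discs and at the floor in wild-type antennal discs, and Hml is at 11.19 in ato-mutant UAS-ey leg discs against 8.26 in UAS-ey leg discs.

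The size of the response differed between discs for some genes, tested as a difference of changes. The rise of eya was larger in leg discs than in wing discs by 2.13 (SE 0.33, adjusted p = 0.00162) and than in antennal discs by 2.01 (SE 0.33, adjusted p = 0.0019). upd1 rose more in leg than in wing discs by 1.93 (SE 0.23, adjusted p = 1.5e-04), Optix by at least 1.45 (adjusted p = 0.0104), and dac rose less (difference -1.09, adjusted p = 2.1e-04). Ilp8, toy and gl were at the floor in both wild types, so their rises cannot be ranked. Their levels with UAS-ey were 10.40 in leg and 7.74 in wing discs for Ilp8, 8.77 and 7.74 for toy, and 10.04 and 8.69 for gl. The differences for so, ato and elav did not pass in any pair of discs. danr rose more in leg (by at least 3.76) and in wing discs (2.70) than in antennal discs, where the wild type already had 11.66. A difference was found for 880 probe sets between leg and wing, 414 between leg and antenna and 177 between wing and antenna. With the phe control as a covariate the first count was 15 and the second 197, and the differences between leg and wing for eya (1.65, SE 0.55) and upd1 (1.62, SE 0.38) were no longer called, mainly because their SE grew. Without wild-type leg replicate 1 the count between leg and wing was 532, and that between wing and antenna was 360 without UAS-ey wing replicate 1 and 286 without wild-type wing replicate 1. Of the calls between leg and wing 38.0% were higher in leg discs, against 57.6% after quantile normalization, and between leg and antenna 39.1%, against 58.8%.

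The genes raised in all 3 discs overlapped far beyond independent lists: 339 probe sets (248 genes) were higher in leg, wing and antennal discs, where independent lists would share 3.51, and 220 were lower, where they would share 2.06. These 3 comparisons share no array. Of the 248 genes, 98 (39.5%) were also higher in the eye disc than in the mean of the other discs, against 10.5% of all genes. The eye comparison reuses the wild-type arrays of the 3 discs, which alone gave at most 6.9% in simulations without an eye difference. They included eya, so, gl, Appl, twit, superdeath and the metalloprotease gene Mmp2, and of these Appl, twit and Mmp2 were raised by 3.12, 2.96 and 2.53 in leg discs. Others in all 3 lists were at the floor on every wild-type array, eye discs included, such as Tektin-C. With the phe control as a covariate, 141 probe sets were called in all 3 discs, all among the 339.

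The wild-type eye disc differed from the mean of the leg, wing and antennal discs first in the retinal genes. gl was at 12.08 ± 0.18 (SD, n = 4) and at the floor on all 9 other wild-type arrays, at least 35.8-fold higher. toy was higher by at least 4.47 (SE 0.11, limma adjusted p = 7.5e-16), eya by 3.56, so by 2.75, Optix by at least 2.56, ato by 2.29, dac by 1.30, elav by 1.30 and sens by 0.87, and hh was lower by -0.83. The bounds arise because toy was at the floor in wild-type leg and wing discs and Optix in wild-type leg discs. Such groups add no spread to the shared estimate, so the SE and adjusted p of toy can understate the spread of the arrays. Of 11 retinal determination genes 7 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 7.4e-07, adjusted p = 0.0738 with an estimated correlation). Of 18 photoreceptor and cone genes 12 were higher and 1 lower (12 and 2 adjusted over the list alone; camera adjusted p = 2.8e-10, and adjusted p = 0.00297 with an estimated correlation). Pan-neuronal genes were higher in 7 of 14 cases (8 adjusted over the list alone; camera adjusted p = 1.6e-05, and adjusted p = 0.0269 with an estimated correlation), with onecut at least 5.36-fold. Of 13 furrow and R8 genes 7 were higher and 2 lower (7 and 3 adjusted over the list alone; camera adjusted p = 8.0e-04, adjusted p = 0.0929 with an estimated correlation).

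Most measured wing and leg identity genes were lower in the eye disc: Dll by -4.18 (SE 0.15), nub at least 10.1-fold, ap at least 8.66-fold and vg at least 7.64-fold. These values are from the representative probe sets. Other nub probe sets changed by 0.01 and -0.05, while those of Dll (-1.12 and -3.22), ap (-1.34) and vg (-1.45) were lower too. Of 14 wing identity genes 11 were lower and 1 higher (12 and 1 adjusted over the list alone; camera adjusted p = 2.0e-09, and adjusted p = 0.0269 with an estimated correlation). Of 14 leg identity genes 10 were lower and 3 higher, also adjusted over the list alone (camera adjusted p = 1.0e-04, and adjusted p = 0.0483 with an estimated correlation). Antenna identity genes went both ways, with 5 of 10 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.14). Of 11 genes of hedgehog, dpp and wingless signalling 7 were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 3.5e-05, adjusted p = 0.101 with an estimated correlation), with inv at -1.85 and en at -1.46. The largest falls also included grn (-2.79) and the cuticle gene Cpr65Ec (at least 6.54-fold), and the largest rises superdeath (at least 31.9-fold higher), Ekar (at least 30.8-fold), the amyloid precursor gene Appl (29.6-fold), the ankyrin gene Ank2 (at least 24.4-fold), twit (18.7-fold) and Mmp2 (at least 12.8-fold). In total 4193 probe sets differed, 1575 higher and 2618 lower. Of the calls, 37.6% were higher, against 48.1% after quantile normalization and 58.9% after centring each array. With the phe control as a covariate 1163 differed and chp passed as higher. Some fat body transcripts were high on 1 eye array alone, replicate 4, with Lsp2 at 12.28, Fbp1 at 12.11 and apolpp at 11.31 against at most 7.49, 7.58 and the floor on the other eye arrays, and without it 4311 probe sets differed. The eye against the antennal disc alone, within 1 array set, gave 1993, with 1020 higher and 973 lower.

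Probe sets raised by ectopic ey were more often higher in the eye disc than other probe sets. Of 1693 raised in leg discs, 353 (20.9%, 95% interval 18.9 to 22.9) were higher in the eye disc than in wing and antennal discs, against 7.3% of all others (odds ratio 3.37, Fisher's exact test, adjusted p = 7.8e-63). The share was 31.3% of 552 for wing discs (95% interval 27.5 to 35.4, against 5.8%, odds ratio 7.41, Fisher's exact adjusted p = 1.7e-72). It was 27.3% of 1322 for antennal discs (24.9 to 29.8, against 7.6%, odds ratio 4.59, Fisher's exact adjusted p = 5.7e-92). Some raised probe sets were lower in the eye disc: 324 for leg discs (19.1%, against 12.9% of all others), 55 for wing discs (10%, against 8.5%) and 178 for antennal discs (13.5%, against 16.7%). Probe sets lowered by ectopic ey were more often lower in the eye disc: 40.1% of 1939 for leg discs (against 10.4% of all others, odds ratio 5.75), 21.9% of 447 for wing discs (against 8.2%, odds ratio 3.14) and 24.1% of 838 for antennal discs (against 16.1%, odds ratio 1.65). The leg set holds the falls that shrank with the phe covariate, and the comparison of eye with wing discs crosses the array sets.

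**Figure D4:**
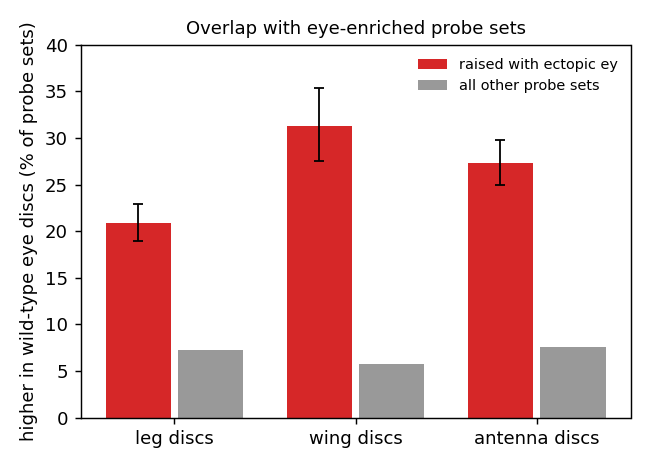
Percent of probe sets that are higher in the wild-type eye disc, among those raised by ectopic ey in each disc and among all others; error bars are 95% binomial intervals. The shares are 20.9%, 31.3% and 27.3% for leg, wing and antennal discs, each above that of all other probe sets (7.3%, 5.8% and 7.6%).

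In ato-mutant leg discs with UAS-ey, retinal genes moved in different directions. Compared with UAS-ey alone, gl fell to the floor, at least 8.76-fold (SE of the log2 change 0.17, adjusted p = 7.2e-10). sens fell by 1.18 (SE 0.15, adjusted p = 2.0e-05), eya by 1.20 (SE 0.23, adjusted p = 0.00108) and dac by 0.61 (SE 0.09, adjusted p = 1.2e-04). so did not pass (-0.04, adjusted p = 1), while Optix rose by 1.34 (SE 0.22, adjusted p = 2.3e-04) and toy by 0.74 (SE 0.16, adjusted p = 0.00199). The ato signal itself fell by 1.73 (SE 0.35, adjusted p = 0.00145), with a wide spread in the mutant (8.81 ± 1.20 against 10.54 ± 0.07). Whether its probe set lies outside the mutated part is not given in the sources used here, so it does not check the genotype. The mutant arrays also spread widely for eya (10.87 ± 0.82), so (9.64 ± 0.65) and Optix (10.63 ± 0.60), while each SE is estimated over all groups. For eya they were at 10.06, 10.86 and 11.70. Replicate 1 was lowest and replicate 3 highest for so, Optix, danr and ato too. Of 13 furrow and R8 genes 5 fell and 1 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.00216, adjusted p = 0.275 with an estimated correlation), among them phyl (-1.28), neur (-0.79) and ro (-0.81). Of 18 photoreceptor and cone genes 6 fell and 5 rose (6 and 6 adjusted over the list alone; camera adjusted p = 0.462), with lz down to the floor, at least 3.52-fold. Antenna identity genes fell in 5 of 10 cases and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.00216, and adjusted p = 0.0304 with an estimated correlation), including danr (-2.09), dan (-1.85) and ss (-1.15). Cell cycle genes fell in 8 of 16 cases, also adjusted over the list alone (camera adjusted p = 0.00576, adjusted p = 0.507 with an estimated correlation). elav (-0.14) and hh (-0.05) did not pass.

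Markers of other tissues rose in the same comparison. Of 12 haemocyte markers 9 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.2e-05, adjusted p = 0.25 with an estimated correlation). Hml, a haemocyte clotting factor gene, went from 8.26 ± 0.15 to 11.19 ± 1.15, Nplp2 rose by 3.67, eater by 3.20 and srp at least 4.34-fold. Of 8 fat body markers 5 rose (7 adjusted over the list alone; camera adjusted p = 0.00516, adjusted p = 0.39 with an estimated correlation), with Apoltp at 2.33. Of 9 salivary gland markers 7 rose (8 adjusted over the list alone, camera adjusted p = 0.00216, adjusted p = 0.419 with an estimated correlation), but only 2 of the 9 were called higher than in wild-type leg discs. Against UAS-ey alone, the salivary genes ng1, ng2 and ng3 rose at least 31.6-fold, at least 30.4-fold and 22.0-fold. Other large rises were Miox (4.45), IM33 (4.31), regucalcin (3.69) and Sp7 (3.64). The largest falls beside gl were Tektin-C (at least 14.1-fold), Hrb87F (-3.28), superdeath (-3.17), Cpr49Ah (-2.76) and Cyp4p2 (at least 5.79-fold). The ratio of 3' to 5' GAPDH control signal was highest in the mutant arrays (log2 difference 2.96 ± 0.29 against 2.13 ± 0.13 in UAS-ey leg discs), and so was the difference between replicate arrays (SD up to 0.448).

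In total 4415 probe sets differed between ato-mutant and other UAS-ey leg discs, 2721 higher and 1694 lower. The share of higher calls was 61.6%, against 32.2% after quantile normalization and 31.1% after centring, which shifted the median change of all probe sets by -0.129. For the genes named here, no direction turned under either scaling. With the phe control as a covariate 311 were called, and the calls for gl, sens, phyl, neur, ro, dan, ss and ng1 held. Calls ended with a larger SE and a change of much the same size for Optix (1.52, SE 0.44), toy (0.71, SE 0.31), dac (-0.54, SE 0.19) and Hml (2.75, SE 0.71). The change was also smaller for ato (-1.20, SE 0.69), eya (-0.77, SE 0.45), danr (-1.63, SE 0.43), Apoltp (1.56, SE 0.52), regucalcin (2.72, SE 0.70), ey (0.51, SE 0.36) and chp (0.83, SE 0.38).

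Against wild-type leg discs, within 1 array set, ato-mutant UAS-ey leg discs still had raised retinal determination genes: Optix at least 13.1-fold, toy at least 6.03-fold, eya by 2.72 (SE 0.23, limma adjusted p = 1.5e-07) and so 2-fold (adjusted p = 0.00123). The wide spread of the mutant arrays for eya, so and Optix applies here too. Of the 11 genes 7 rose and 1 (dac, -0.38) fell (8 and 1 adjusted over the list alone; camera adjusted p = 8.2e-05, adjusted p = 0.405 with an estimated correlation). gl was at the floor in both groups, sens fell by 1.38 (SE 0.15), and ato (-0.25), elav (0.50), ey (0.49), chp (0.45) and hh (-0.15) did not pass, though ato was called lower (-0.93) when mutant replicate 3 was left out. Of 14 Notch and E(spl) complex genes 4 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.0156, adjusted p = 0.452 with an estimated correlation). Of 14 leg identity genes 8 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0204, adjusted p = 0.405 with an estimated correlation), with Scr at -1.33. Haemocyte markers rose in 9 of 12 cases, also adjusted over the list alone (camera adjusted p = 2.8e-05, adjusted p = 0.405 with an estimated correlation). Of 8 fat body markers 4 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0554), with a median change of 1.67. Of 9 salivary gland markers 2 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.958), with a median change of -0.26. Sgs3 was at 9.33 in the mutant, 10.57 in wild-type and 7.67 in UAS-ey leg discs. The log2 difference between 3' and 5' GAPDH signal was 2.96 ± 0.29 in the mutant and 1.84 ± 0.08 in wild-type leg discs. Among named genes, the largest rises were IM33 at least 32.4-fold, ng1 at least 31.6-fold, ng2 at least 30.4-fold, Miox 27.0-fold, ng3 25.2-fold, Pxt at least 23.8-fold, Cyp6a17 at least 20.1-fold and fon 17.9-fold. The largest falls were Hrb87F (-3.20), Sgs5bis (at least 5.48-fold), Kmn1 (-2.31), vis (at least 4.68-fold), Zip102B (-2.16) and spt4 (-1.96). In total 3968 probe sets differed, 2303 higher and 1665 lower. Higher calls made up 58.0%, against 36.1% after quantile normalization and 37.3% after centring, and a fit on these 6 arrays alone called 1320.

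Of the 1693 probe sets raised by UAS-ey in leg discs, 884 (52.2%) were also higher in ato-mutant UAS-ey than in wild-type leg discs, where independent lists would share 207.7. Of 1939 lowered by UAS-ey, 685 (35.3%) were also lowered in the mutant, where independent lists would share 172. Both comparisons use the same wild-type arrays, so the lists are not independent, and simulations without an effect in the mutant gave at most 7% and 4%. Their log2 changes correlated with r = 0.287 across 15516 probe sets, where unchanged groups against those controls gave 0.501, and had the same sign in 57.8% of cases against 66.6% simulated. The covariance was 0.0582 against 0.00956 simulated, a difference of 0.0486. The 52.2% became 33.0% after quantile normalization, 32.6% after centring and 74.2% with the phe control as a covariate. Compared with UAS-ey alone, 588 of the 1693 raised probe sets (34.7%) were lower in the mutant. Of the 1939 lowered, 962 (49.6%) were higher in the mutant than with UAS-ey alone. That comparison crosses the array sets.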

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

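All tests of explanations in this part were chosen after the results were seen, except the counts over other groupings of the arrays and the share of flight muscle genes not looked at before that rose. The difference between the effects of ectopic ey in 2 discs was tested for each probe set, and it passed for 880 probe sets between leg and wing discs, 414 between leg and antennal discs and 177 between wing and antennal discs. Of 100 groupings of the arrays, 10 gave as many between leg and wing (highest other 4265), 5 between leg and antenna (551) and 10 between wing and antenna (4749). By design all these groupings exchange arrays between the 2 discs, within ectopic ey or within wild type. They so can put the differences between discs into the contrast, a structure of the samples. In the groupings with the highest counts wild-type arrays were exchanged. They therefore give no measure of chance for these counts.

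Between leg and wing discs, the effect of UAS-ey was larger in leg discs for eya (2.13) and upd1 (1.93), in log2 units. Ilp8 (2.66), Cyp6a17 (1.76) and Elovl7 (1.63) also passed, but both wild types were at the floor, so these values compare levels with UAS-ey and do not rank the rises. It was smaller for CSN1a (-3.22), Timp (-2.88), Pvf1 (-2.83), CNT2 (-2.82) and Cyp9b2 (-2.82), which fell in leg discs and did not pass in wing discs. With the phe control as a covariate the calls for eya (1.65), upd1 (1.62), Elovl7 (1.49), CSN1a (-0.31), Timp (-0.31), Pvf1 (-0.39) and Cyp9b2 (-0.53) ended, and CNT2 turned (0.68). The SE rose from 0.33 to 0.55 for eya and from 0.23 to 0.38 for upd1, whose calls ended mainly for that reason, whereas the difference for CSN1a shrank (SE 0.60 and 0.49). Among genes of eye development it differed for ey (-1.76), dac (-1.09), Optix (at least 1.45) and chp (-2.18), and the levels with UAS-ey, from the floor in both wild types, for toy (1.03) and gl (1.35), while the ey and chp signals also moved with the phe control within groups.

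Between leg and antennal discs, the effect was larger in leg discs for eya (2.01), and by at least the value given for danr (3.76), spok (3.16), dan (2.61) and toy (1.54), which started or ended at the floor in a group. Cpr49Ah (2.01) and gl (1.10) were at the floor in both wild types, so only levels with ectopic ey are compared. The effect was smaller for Mlc1 (-4.54), eEF1alpha2 (-4), dac (-1.20) and chp (-1.65), and for Act88F by at least the value given (-6.40). fln (-5.73) and TpnC4 (-4.66) were at the floor in both leg groups, so their change in leg discs was not measured and the values are those against the floor. The difference for spok was lost in 11 of 12 fits with an array left out, with values of up to 3.24.

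Between wing and antennal discs, the effect was larger in wing discs for Cpr51A (2.86), danr (2.70), cpo (1.46) and dan (at least 1.79). Another cpo probe set changed by 0.52 in wing and 0.62 in antennal discs, so the difference for cpo rests on its representative probe set. For skl (1.48), at the floor in both wild types, only levels with ectopic ey are compared. The effect was smaller for Mlc1 (-3.87), and by at least the value given for Act88F (-6.61) and COX7AL2 (-3.60). fln (-5.73) and TpnC4 (-4.66) were at the floor in both wing groups, so the values are those against the floor. The difference for skl was lost after quantile normalization (1.34) and in 11 of 12 fits with an array left out, with 1.28 without UAS-ey wing replicate 1.

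In the wild-type eye discs, 1 array stood apart from the other 3 for 5 of 88 genes tested. Of the 82 genes named by the rule 3 did so, not more than the 1 gene in 20 that chance gives. The remaining genes were plotted as genes of other tissues, so their values do not count against chance. The gaps were small for onecut at 9.54 in replicate 3 (others 9.24 to 9.29) and E(spl)m4-BFM at 11.94 in replicate 2 (others 11.75 to 11.77). On replicate 4 they were larger, and all 3 were fat body genes: apolpp at 11.31 (others at the floor), Fbp1 at 12.11 (others 7.39 to 7.58) and Fbp2 at 8.39 (others 6.91 to 7.10). Of the 8 fat body markers measured, 4 stood apart on replicate 4, the fourth being Lsp2 at 12.28 (others 7.23 to 7.49), against 0 of 12 haemocyte, 0 of 9 salivary gland and 1 of 8 muscle precursor markers (Tm2, 7.75 against 7.65 to 7.67). Replicate 4 thus carried some fat body transcripts at levels that the other eye arrays did not have.

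The comparison of UAS-ey with wild-type leg discs crosses the array sets that the phe control separates, and 395 probe sets fell and 176 rose at least 2-fold in it. For the falls, the slope on phe within groups and the gap of -2.05 in phe gave a median of 77% of the change (-40.2% to 46.5% with permuted phe values), and 17% (95% interval 13.4 to 21%) also fell in wing or antennal discs, above the 5.3% of all probe sets, which argues against an effect of ey shared by the discs for most of them but not for all. With the covariate their median change went from -1.51 to -0.39 and the median SE from 0.28 to 0.32, so that 54 were still called, mainly because the changes shrank. For the rises, the same slope gave 2.7% of the change (-5.6% to 8.3%), which argues against a set difference that follows phe as their cause. A set difference that does not follow phe within groups would not show in this slope. Of the rises 86.4% (80.4 to 91.1, against 7.8% of all probe sets) also rose in wing or antennal discs, as an effect of ey that the discs share would give. In ato-mutant UAS-ey against wild-type leg discs, within 1 array set, 76.7% of the rises (69.8 to 82.7) but 14.2% of the falls (10.9 to 18%) were called again, where the shared wild-type arrays alone gave at most 15.1% and 5.6% in simulations without an effect, which argues against an effect on leg discs that needs no ato for most falls and leaves open 1 that needs ato.

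Flight muscle genes rose in Uey antennal discs, and 0 of the 6 seen first (median change 4.28) were higher in leg or wing discs. Among them Act88F, fln, TpnC4 and Mlc1 were flagged because their changes differed between discs. The 0 of 6 thus restates that difference and is no separate test of an effect of ey shared by the discs. Flight muscle tissue or its RNA in the Uey samples stays open. Of 16 further flight muscle genes chosen before their values were seen, 25% (4 genes, 95% interval 7.3 to 52.4) were higher, namely up (2.42), bt (0.98), Zasp52 (0.44) and Actn (0.42), with a median change of 0.16 over the 16, a share that does not decide it. An effect of Uey confined to the antennal disc was not tested and also stays open.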

How the results depend on the processing

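The covariate, the fit without probe sets at the floor on all arrays, and the eye against the antennal disc were alternatives chosen after seeing the data. Pseudocounts were not run, since the values were already on a log2 scale. Signals near the floor limit the smallest changes that can be seen. Over 572 pairs of a named gene and a comparison, call and direction were kept in 544 with quantile normalization, 529 with centring, 503 with array weights, 449 in fits on the compared groups only, 570 with trend and robust settings, 555 with the replicate number as a block and 439 with the covariate. They were kept in 4001 of 4242 fits without an array, and in 532 of 552 pairs with the filter above the 40th percentile. Without probe sets at the floor on all arrays, 559 were kept. With the mean of all probe sets of a gene, only 61 of 80 pairs with several probe sets were kept. There 8 calls were lost, 8 were gained and 3 directions were reversed. Where values moved, the cause was not tested.

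With the phe covariate the counts were 561 for leg (3632), 311 for ato-mutant against UAS-ey leg (4415), 1163 for eye (4193), 15 for leg against wing (880), 197 for leg against antenna (414) and 141 in all 3 discs (339). The eye share was 28.1% (20.9%) and the ato share 74.2% (52.2%). Array weights, from 0 to 11.5, gave 2274 for wing (999), 5884 for antenna (2160), 2119 for ato-mutant against UAS-ey leg, 2047 for ato-mutant against wild-type leg (3968), 7856 for eye, 2779, 2350 and 1796 (177) for the leg-wing, leg-antenna and wing-antenna differences, and shares of 27.5% and 30.7%. Fits on the compared groups only estimate the variance from fewer arrays and from the spread of those groups alone, and their counts moved in both directions. They gave 2268 for leg, 138 for wing, 4114 for antenna, 1969 and 1320 for the ato-mutant comparisons, 335 and 1096 for the leg-wing and leg-antenna differences and an eye share of 23.7%. Quantile normalization gave 1440 and 626 for these differences and an ato share of 33.0%. Centring gave 625 for wing, an eye share of 24.5% and an ato share of 32.6%. A 2-fold minimum, stricter by construction, left 571 for leg, 143 for wing, 271 for antenna, 851 and 534 for the ato-mutant comparisons and 624 for eye. The eye against the antennal disc alone gave 1993.

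Without single arrays the counts ranged from 2578 to 3905 for leg, 704 to 1024 for wing, 1558 to 1745 for antenna, 3081 to 4618 and 2838 to 4069 for the ato-mutant comparisons and 3210 to 5349 for eye. The differences ranged from 532 (without wild-type leg replicate 1) to 1282 for leg-wing, 278 to 538 for leg-antenna and 132 to 360 for wing-antenna (360 without UAS-ey and 286 without wild-type wing replicate 1). Probe sets raised in all 3 discs ranged from 261 to 330, the eye share from 19% to 25% and the ato share from 44.7% to 59.1%.

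Of 150 gene list tests 41 were called, 6 with an estimated correlation and 82 with fry, which tests another hypothesis. Directions reversed with the mean of all probe sets for Galphaq in UAS-ey (0.32) and ato-mutant (0.38) against wild-type leg discs and for Sxl in the eye disc (0.20), and with the covariate for vkg in leg discs (0.19) and the leg-wing difference of CNT2 (0.68). The replicate numbers did not pair the samples (mean r -0.022 within a number, 0.01 between numbers).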

Other observations

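The tests of the genes raised in all 3 discs were chosen after the result was seen, while the groupings of the arrays were planned. Ilp8, upd1, ftz-f1 and chinmo rose with ectopic ey in several comparisons. Ilp8 rose in ato-mutant UAS-ey against wild-type leg discs too, at least 4.58-fold, and upd1 by 2.11. The nuclear receptor gene ftz-f1 rose in leg (2.01), wing (1.56) and antennal discs (1.80), and by 2.42 in ato-mutant UAS-ey against wild-type leg discs. chinmo, a BTB zinc finger gene active in early larval stages, rose by 3.17, 2.61 and 2.76 in the 3 discs and by 3.38 in the ato-mutant leg discs. In antennal discs 4 of 14 ecdysone response genes fell and 2 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.194), with Hr3 at -1.10 and Hr4 at -0.89.

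Cuticle, tracheal and glial markers were measured beside the retinal genes. In ato-mutant against other UAS-ey leg discs 3 of 5 cuticle protein genes rose (3 higher and 1 lower adjusted over the list alone), with Edg91 at 2.29, and 3 of 8 glial markers rose and 1 fell (4 and 2 adjusted over the list alone), with Gs2 at 1.56. In UAS-ey against wild-type leg discs, 4 of 8 glial markers fell and 2 rose, also adjusted over the list alone. There, 3 of 7 tracheal markers rose and 1 fell (3 and 3 adjusted over the list alone), with the FGF gene bnl at 1.17. In wing discs 4 of 10 antenna identity genes rose, dan, danr, lz and ato (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0163, adjusted p = 0.11 with an estimated correlation).

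Among probe sets at least 2-fold higher with ectopic ey in all 3 discs, 47 were not higher in the wild-type eye disc (8 of them, such as Tektin-C, at the floor on all wild-type arrays) and 27 were. The 47 rose by more similar amounts across discs, with a median SD of the 3 changes of 0.23 against 0.38 (permutation p = 0.0194), which is consistent with the genetic background of the fly stocks as their source. Of them 85.1% (40) were also higher in ato-mutant UAS-ey than in wild-type leg discs, where the shared wild-type arrays alone gave at most 6.6% in simulations without an effect. An effect of ey that needs no ato would equally give this share. However, 15 of the 47 were lower in the mutant than in UAS-ey leg discs, with Tektin-C at the floor in the mutant. The GAPDH control ratio was also higher with ectopic ey in all 3 discs, but its slope within groups gave -1.1% of the changes (-2.8% to 2.6% with permuted values), which argues against RNA integrity or labelling length that follows this ratio. The other 2 stay open, since a control with the same background and no UAS-ey was not analysed here.

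The same counts were made for other groupings of the same arrays. For the eye disc 1 of 100 groupings, the real one, gave as many (4193, highest other 3272, in a grouping that kept the eye arrays together). These groupings mix arrays of different discs, so they give no clear measure of chance for the eye count. For the probe sets raised in all 3 discs, arrays were exchanged within each disc. There 1 of 100, the real one, gave as many (339, highest other 1), a share of groupings under 0.05. With 3 against 3 arrays there are only 10 groupings, too few for a share under 0.05. The real and highest other counts were 3632 and 1 for leg, 999 and 386 for wing, 2160 and 1 for antenna, 4415 and 3 for ato-mutant against UAS-ey leg, and 3968 and 50 for ato-mutant against wild-type leg discs. The shares were 20.9% and 0 for the eye disc, and 52.2% and 0 for the ato mutant. These 0 values give no measure of chance. The other groupings called at most 1 probe set in leg discs, and the share of an empty list was set to 0.

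Probe sets beyond the controls also followed the array sets. Splitting the 8 groups 4 against 4, the phe control's array sets were separated fully by 550 probe sets, 58 of them with a gap over 0.5, where the next of 35 such splits (ectopic ey against wild type) had 274. The sets also differ in tissue and genotype. In UAS-ey leg, antennal and eye discs danr was at 10.67 or above, against 9.86 or below in the other set. For ato the limits were 10.47 and 10.16. The count of 550 thus does not tell a technical difference from a biological one.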
